A study of Mus musculus with 8 samples.

How the data were processed

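The labels give total RNA from mouse liver or purified ER and an Illumina library protocol, without naming a selection of polyadenylated RNA. STAR 2.3.0e, DESeq2 1.6.3 and the mm10 build are named, without their roles, per the submitters' processing notes. The annotation, the counting tool, its strand setting and its treatment of reads that map to several places are not given in the sources used here. The series has 2 deposited tables, each with 6 numeric columns for 1 comparison, which hold neither sample names nor values per library. For each gene the authors gave a mean signal (the mean of counts divided by size factors, per the file headers), a log2 fold change with its standard error on the log2 scale, a Wald score, and a p-value with its adjusted p-value, all per the file headers. The score equals the log2 fold change over its standard error in every row. The largest standard errors among tested genes were 0.123 in the larger table and 0.142 in the smaller, and low genes had fold changes near 0, as the moderated estimates that DESeq2 gives by default in the authors' version do.

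An adjusted p-value is missing in the deposited tables for 9454 and 9540 genes, and all of them have a lower mean than every gene with one. The lowest means with an adjusted p are 17.4 and 31.9 counts. Genes without an adjusted p were left out of the tests. Gene identifiers were matched to GENCODE mouse release M21 names (GRCm38, the assembly that mm10 names), with 23484 of 23634 and 21080 of 21201 matched. Called genes are those under the authors' adjusted p of 0.05.

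The design fixed before the data were examined was a quasi-likelihood test of counts per preparation, with tests of ER against total liver and of the genotype difference between preparations. It needs values per library, so it was not run, and the authors' own Wald test stands in its place. The comparison of ER with total liver and of each library's Cpeb4 level was not made. Which preparation each table covers is not written in the labels or headers and was left open. The labels do not say that the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. The description numbers 6 to 9 recur in the ER and total liver libraries and may mark the same mice, although their sample names differ. No count of libraries showing a direction can be given beside any gene, and no interval of counting error.

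The depth of the libraries was read from the tables. Genes with a single read have a mean of 1 read over the number of libraries, scaled by that library's size factor, so the lowest values repeat in steps. Relative depth is the size factor that each step implies. The deepest library was 1.75 times as deep as the shallowest in the larger table and 1.96 times in the smaller. No step was assigned to a sample. The smallest difference that can pass depends on the standard errors, whose medians were 0.107 and 0.128 on the log2 scale.

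From the deposited values, 40 gene lists fixed before the data were examined were tested against all other tested genes with limma 3.58.1 (cameraPR, on the Wald statistics, preset correlation 0.01, lists of at least 5 measured members, Benjamini-Hochberg adjustment over the lists of each table) in R 4.3.3. An estimated correlation between genes needs values per library, so none was computed, and which calls would hold with it is unknown. Preset correlation 0.05 was tried in its place. For each list the text gives members past the authors' test over all genes, and members past a Benjamini-Hochberg adjustment over the list alone. Of 71 list tests, 11 had a median log2 fold change or mean statistic of the other sign than the test, and none of the 11 passed.

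The difference between the tables was tested per gene as the smaller table's log2 fold change minus the larger table's, over the root of the summed squared standard errors (z test, Benjamini-Hochberg over 11604 genes), and per list with cameraPR on these z values. This treats the tables as independent. Positive covariance between them makes the test conservative; the z values had an SD of 0.535. Pearson's r and Spearman's rho were computed across genes. The share of each gene's 31-base words that occur in another annotated gene, and the number of overlapping genes, came from GENCODE M21 transcripts. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used.

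Both computations were tested on simulated data. With 6 lists shifted by 1 SD among 14180 genes of the larger table, the list test recovered 91.7% of them in 50 draws. Of unshifted lists, 5.0% had a p under 0.05. These rates describe simulated lists, and the correlation within real lists was not estimated. They do not show how often the list test errs where members vary together more strongly than the preset correlation. For the difference between tables, 200 of 11604 genes were changed, and 60.0% of log2 differences of 0.6 and 98.9% of differences of 1.0 were recovered, with 4.9% of calls false. Both simulated tables were drawn independently from the standard errors that the test itself uses, with changes added unmoderated. The share of false calls follows from that setting. The real z values had an SD of 0.535, so these rates describe the simulated draws and not the real test.

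Named genes follow a rule fixed at the same time. Cpeb4 comes first, then per table the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM, then up to 4 members per list by adjusted p, and up to 10 genes for the difference between tables. Its further condition, that the libraries of both genotypes do not overlap, could not be applied. CPM is the mean signal scaled to the sum over the table, so 1 CPM is a mean of 37.4 in the larger table and 36.8 in the smaller. Results of some genes that this rule names are not reported here. Alternatives tried were no mean filter (adjustment over all genes), a mean of at least 5 CPM, statistics divided by their robust SD, exclusion of genes with over 25% shared words, list tests on ranks and at the other preset correlation, and a difference of Wald statistics.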

Results

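RNA was sequenced from livers of mice lacking Cpeb4 and of wild-type mice. Cpeb4 encodes a cytoplasmic polyadenylation element binding protein, an RNA-binding protein that acts on the poly(A) tail and translation of its target mRNAs. The 8 libraries fall into 4 groups of 2, namely knockout and wild-type total liver RNA, and knockout and wild-type RNA from purified endoplasmic reticulum (ER). The labels state that the ER preparations came from mice fasted overnight. They do not state the feeding state of the mice behind the total liver RNA, nor whether the same mice gave both preparations. The comparison asks which transcripts differ between the genotypes in each preparation, in a series whose title names hepatic steatosis.

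The values used here are 2 deposited tables of the authors' own genotype comparison, called the larger table (23634 genes) and the smaller table (21201 genes). Neither table names its RNA preparation, so neither is assigned to total liver or to ER here, and no comparison of ER with total liver was made. The tables give 1 value per gene and no value per library. Their lowest mean counts still show the reads behind them. All 5177 genes of the larger table and all 4801 of the smaller table with a mean under 2 were whole combinations of 4 single-read steps, within a tolerance of 1e-06. Each table therefore rests on 4 libraries, and the signs of genes with a single read put 2 of them on each side of the comparison. The relative depths of the 4 libraries ran from 0.717 to 1.26 in the larger table and from 0.839 to 1.64 in the smaller table.

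Cpeb4 itself was lower in the knockout in both tables. The gene (ENSMUSG00000020300; GRCm38 chromosome 11, 31872211 to 31935634, plus strand, protein coding) had the smallest p of each table. Its log2 fold change was -1.16 ± 0.11 (SE) in the authors' deposited larger table (mean count 1063, adjusted p = 3.18e-24) and -1.10 ± 0.13 in the smaller (mean count 435, adjusted p = 2.30e-12). The tables write neither the compared groups nor the direction. Since Cpeb4 had the smallest p in both, the comparison was read as one of genotype, with its negative sign as lower in the knockout. All directions below rest on that reading, so the value of Cpeb4 is not an independent check of the labels, and its level in single libraries was not analysed here. The deposited fold changes are moderated, that is, drawn towards 0, so they understate changes and the remaining Cpeb4 signal is not a measure of residual transcript. Cpeb2, a paralog of Cpeb4, was higher in the knockout, by 0.48 ± 0.11 in the authors' deposited larger table and 0.65 ± 0.13 in the smaller (adjusted p = 0.00305 and 0.00139). Another paralog, Cpeb3, had 0.14 ± 0.12 and 0.34 ± 0.14 and did not pass in either deposited table. Of the CPEB and cytoplasmic polyadenylation list, 14 and 13 members were measured, and apart from Cpeb4 and Cpeb2 none of them passed, in the larger and smaller table in turn, among them Parn and Tent2; the same 2 genes passed when adjusted over the list alone. The list as a whole did not stand apart from other genes (camera adjusted p = 0.672 and 0.810).

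In the authors' deposited larger table, 42 of 14180 tested genes passed an adjusted p of 0.05, 13 higher and 29 lower in the knockout. The largest increase was that of Gadd45g, a stress-inducible growth arrest gene, at 0.85 ± 0.12 (adjusted p = 3.74e-09). Other increases were those of Tat (tyrosine aminotransferase) at 0.70 ± 0.11, Etnppl (ethanolamine-phosphate phospho-lyase) at 0.62 ± 0.11 and Fh1 (fumarate hydratase) at 0.53 ± 0.10 in the same deposited table. Ren1, which encodes renin, rose by 0.64 ± 0.10 at a mean count of 76.7 in the deposited table. Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, Mmd2, Slc25a25, a mitochondrial carrier, and Pdia5, a protein disulfide isomerase, rose by 0.51, 0.51, 0.42 and 0.40 per the authors' deposited table. So did Hamp, the iron-regulatory hormone hepcidin, and its neighbour Hamp2, by 0.47 and 0.36 in the same deposited table.

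The decreases in the authors' deposited larger table included genes of lipid metabolism. The fatty acid uptake receptor Cd36 was at -0.62 ± 0.12, and 4 stearoyl-CoA desaturases, Scd1, Scd2, Scd3 and Scd4, lay between -0.57 and -0.53 in that deposited table. Serpina12 (vaspin, -0.60 ± 0.11), the G-protein regulator Rgs16 (-0.60 ± 0.12), the nucleic acid sensor Zbp1 (-0.57 ± 0.12), Lgals1 (galectin-1, -0.54 ± 0.11), the methyltransferase Inmt (-0.50 ± 0.10) and Coro2a (-0.49 ± 0.11) completed the 12 largest decreases of the deposited table. A further 15 genes passed at smaller changes, from -0.49 for Car3 to 0.35 for Igfbp2 in the authors' deposited table, and among them were Iigp1, Srebf1, Elovl3, Pltp, Aqp8, Ces1f, Gstt1 and the cytochromes P450 Cyp2a4, Cyp2a5 and Cyp2c29. Another 3, BC018473, Ifi213 and Ifi206, passed at a mean under 1 CPM.

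In the authors' deposited smaller table, 31 of 11661 tested genes passed, 19 higher and 12 lower in the knockout. Besides Cpeb4, Serpina12 (-0.70 ± 0.12), Lgals1 (-0.69 ± 0.12), Inmt (-0.63 ± 0.11), Zbp1 (-0.59 ± 0.13), Cyp2d40 (-0.51 ± 0.13), Scd1 (-0.47 ± 0.11), the glutathione transferase Gstt1 (-0.44 ± 0.11) and the interferon-induced Bst2 (-0.43 ± 0.11) were lower in the authors' deposited table, as were Gm15890 and Gm43302. The largest increases in that deposited table were those of Fmn2, a formin, at 0.75 ± 0.14, Gadd45g at 0.73 ± 0.13, Tat at 0.72 ± 0.12, Trim30a at 0.69 ± 0.12, Ppargc1a at 0.67 ± 0.13 and the phosphodiesterase Pde1c at 0.66 ± 0.14. Etnppl (0.64 ± 0.12), G6pc (the glucose-6-phosphatase that releases glucose, 0.58 ± 0.13), Mmd2 (0.57 ± 0.14), Serpina1e (0.56 ± 0.13) and the organic anion transporter Slco1a4 (0.56 ± 0.13) followed per the authors' deposited table. The other 7 called genes rose by 0.43 to 0.55 in that deposited table, and among them were Cth and Got1, enzymes of cysteine and aspartate metabolism, and Slc25a15 and Slc7a2, carriers of ornithine and of cationic amino acids.

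Some called genes share sequence with other annotated genes, so that reads could be split between copies. Over 25% of the 31-base words of 6 called genes of the larger table (Hamp, Hamp2, Cyp2a4, Cyp2a5, Ifi206 and Ifi213) and of 4 of the smaller (Serpina1e, Gm15890, Gm43302 and Cyp2d40) also occur in another gene. Their values are uncertain for that reason. The values of Scd2, Scd3 and Scd4 are uncertain as well, because their mean counts were 65.7, 68.0 and 136 times higher in the authors' deposited larger table than in the smaller, against 1.6 times for Scd1 (the tables were normalised separately). Cpeb2 and Ppargc1a overlap 3 and 4 other annotated genes, and whether counting used strand is not given in the sources used here.

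**Figure D1:**
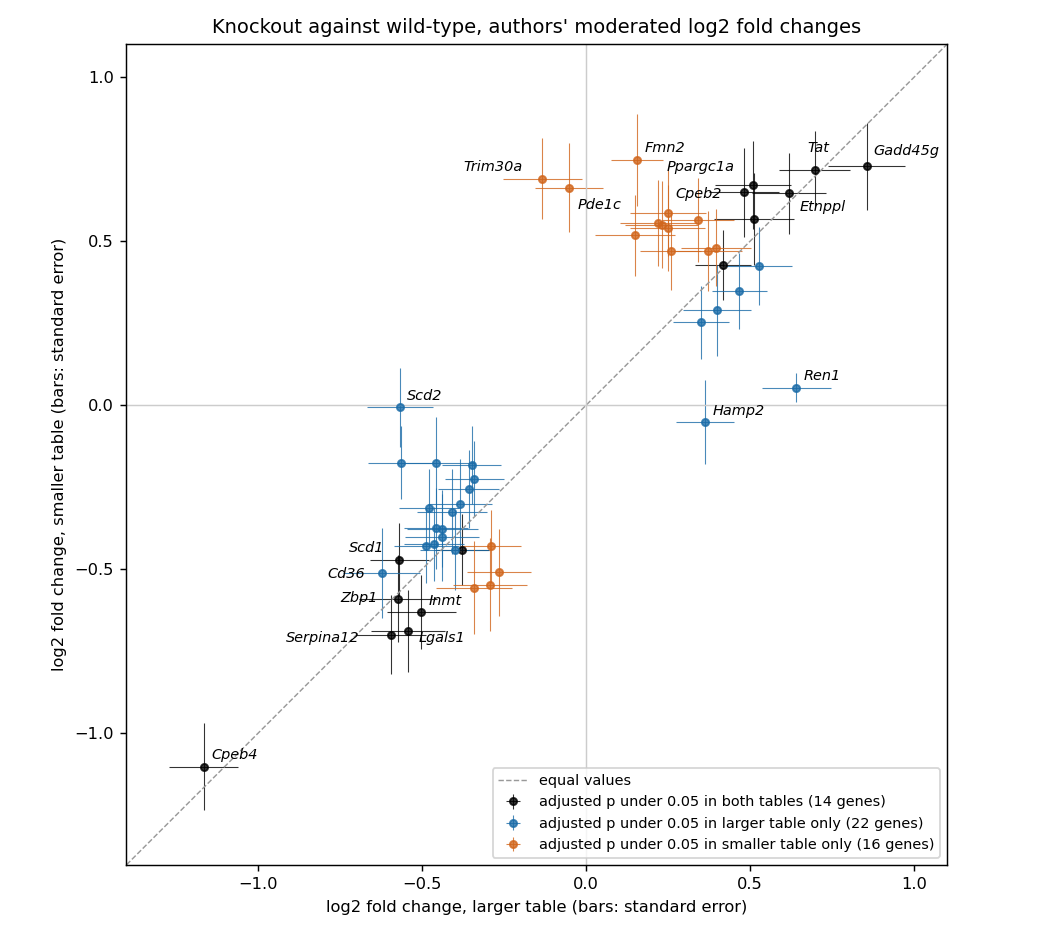
Moderated log2 fold change of knockout against wild-type in the authors' deposited larger table (x axis) and smaller table (y axis), with bars of 1 standard error, for genes reported here that were tested in both tables and past an adjusted p of 0.05 in at least 1. Black points are the 14 genes past in both tables, from Cpeb4 at the lower left to Gadd45g at the upper right, and Ren1 and Trim30a lie far from the dashed line of equal values.

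Transcripts of fatty acid and triglyceride synthesis were lower in the knockout. In the larger table, 21 of 24 measured members had negative fold changes and the list lay below other genes (camera adjusted p = 1.73e-13), and in the smaller table, 16 of 24 did (2.50e-05). Scd1, Scd2 and Srebf1, the transcription factor SREBP1, passed the gene test in the larger table and Scd1 in the smaller. The value of Scd2 in the larger table is uncertain, as given above, and at 6.8% shared words the exclusion of genes sharing sequence kept it. With no mean filter Srebf1 did not pass (Wald test, adjusted p = 0.0748). Adjusted over the list alone, 8 and 7 members were lower, and 21 and 23 did not pass over all genes. Members that did not pass over all genes included Pklr (-0.33 and -0.27), Fasn (-0.27 and -0.35) and Mid1ip1 (-0.30 and -0.45) in the authors' deposited tables. The smaller table's call was lost on ranks (camera adjusted p = 0.0505). Lists of lipid handling were lower as well. Of lipid droplet proteins and lipases, 15 of 23 and 15 of 22 members had negative values (camera adjusted p = 0.00157 and 0.000187), with 1 member, Cd36, past the gene test in the larger table, and 2 and 3 lower when adjusted over the list alone. The larger table's call was lost on ranks, with a camera adjusted p of 0.0529. Of lipoprotein assembly and secretion, 14 and 13 of 17 members were negative (camera adjusted p = 0.000163 and 0.0104), and 1, the phospholipid transfer protein Pltp, passed in the larger table (-0.38 ± 0.10 in the authors' deposited table), and it alone when adjusted over the list alone. The smaller table's call on that list was lost at a preset correlation of 0.05 (camera adjusted p = 0.0637).

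PPAR-alpha targets of fatty acid oxidation and ketogenesis had 21 of 34 members below 0 in each table, and none passed the gene test, nor when adjusted over the list alone. The list test passed in the smaller table (camera adjusted p = 0.00515, 0.0805 on ranks and 0.0769 at a preset correlation of 0.05) and did not in the larger (0.135). Vnn1, at -0.25 and -0.39 in the authors' deposited tables, was the member named in both. SREBP2 targets of cholesterol synthesis did not stand apart (camera adjusted p = 0.881 and 0.648), with 12 of 23 and 11 of 22 members above 0 and none past the gene test or when adjusted over the list alone.

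Genes of gluconeogenesis and the fasting response were higher in the knockout, with 13 of 20 members of the larger table and 12 of 19 of the smaller above 0 (camera adjusted p = 5.29e-05 and 0.000187). Tat and Ppargc1a rose in both tables, and G6pc and Got1 in the smaller. When adjusted over the list alone, 2 members were higher in the larger table, and 5 were higher and 1 lower in the smaller. The remaining members, 18 and 14, did not pass over all genes, among them Igfbp1 at 0.21 ± 0.09 and 0.19 ± 0.10 in the authors' deposited tables. Both calls were lost on ranks (camera adjusted p = 0.0529 and 0.116). Immediate early genes were higher too, with 15 of 19 and 12 of 16 members above 0 (camera adjusted p = 3.02e-09 and 2.85e-06). Gadd45g passed the gene test in both tables, 4 members were higher in each when adjusted over the list alone, and Myc had 0.43 ± 0.12 and 0.41 ± 0.14 in the authors' deposited tables without passing over all genes.

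The zonation list, which joins genes of hepatocytes near the portal vein and near the central vein, lay above other genes (camera adjusted p = 0.0335 and 0.00188), with 14 of 21 and 14 of 20 members above 0. Its only called member, Cyp2a5, fell in the larger table (-0.46 ± 0.09 in the authors' deposited table), and when adjusted over the list alone 3 and 6 members were higher and 1 in each table lower. Members above 0 that did not pass over all genes were the urea cycle enzymes Arg1 (0.37 and 0.38), Cps1 (0.21 and 0.43) and Asl (0.26 and 0.35) in the authors' deposited tables. On ranks neither call held (camera adjusted p = 0.072 and 0.0575), nor did the larger table's at a preset correlation of 0.05 (0.128).

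Interferon-response genes were lower in the knockout as a group. All 26 measured members had negative fold changes in each table, with medians of -0.20 and -0.24 (camera adjusted p = 6.08e-21 and 2.69e-20). The group moved by small steps, since 1 member passed the gene test in each table, the GTPase Iigp1 in the larger (-0.48 ± 0.09) and Bst2 in the smaller (-0.43 ± 0.11, both in the authors' deposited tables), and 25 did not. Adjusted over the list alone, 7 and 8 members were lower. Irf7 (-0.31 and -0.43) and Isg15 (-0.38 and -0.48) were among those that did not pass over all genes in the authors' deposited tables. Markers of Kupffer cells and macrophages were lower beside them, with 16 of 19 and 17 of 18 members below 0, medians of -0.08 and -0.10, and no member past the gene test, nor when adjusted over the list alone (camera adjusted p = 0.0125 and 0.00242). The larger table's macrophage call was lost at a preset correlation of 0.05 (camera adjusted p = 0.0662).

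Erythroid markers were lower too, with 5 and 6 of 7 members below 0 and medians of -0.29 and -0.36 (camera adjusted p = 2.02e-05 and 1.38e-05). No member passed over all genes, and 4 were lower in each table when adjusted over the list alone. These 4 were the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, from -0.30 to -0.29 and from -0.42 to -0.36 in the authors' deposited tables. Over 50% of their sequence words are shared with another gene, and the smaller table's call was lost on ranks (camera adjusted p = 0.0721).

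**Figure D2:**
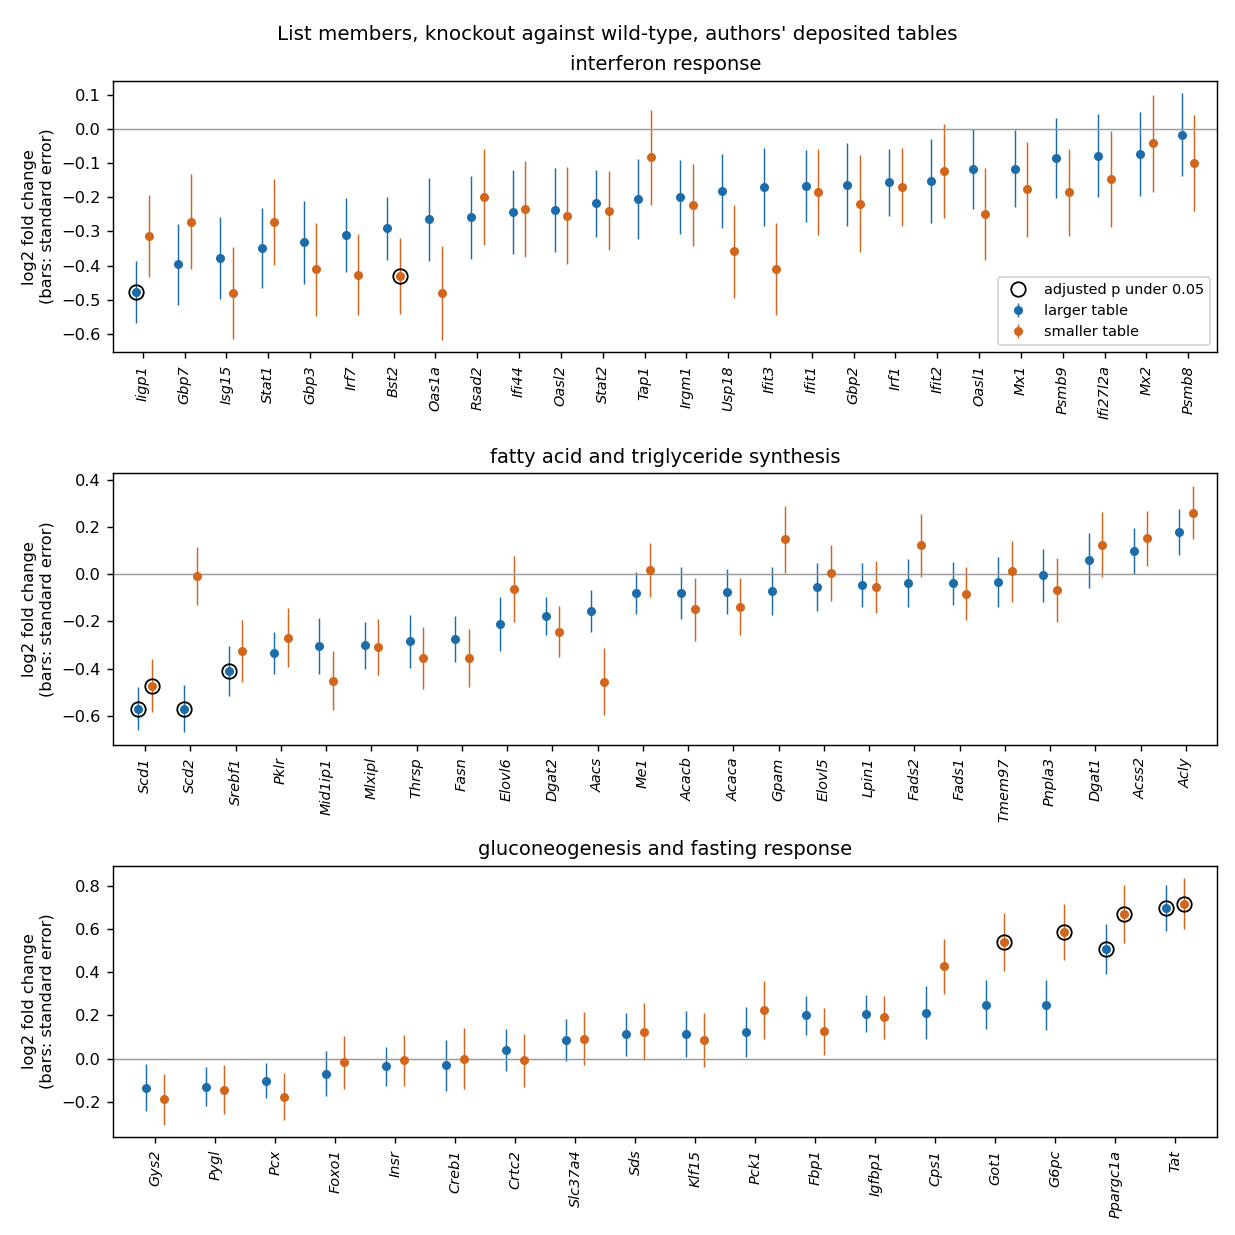
Moderated log2 fold change of knockout against wild-type for the members of 3 gene lists that are reported here and were tested in both of the authors' deposited tables, with bars of 1 standard error; blue is the larger table, orange the smaller, and a ring marks an adjusted p under 0.05. All 26 interferon-response members lie below 0 in both tables, whereas synthesis and fasting members lie on both sides of 0, with few called.

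Lists of ER proteins, the compartment purified for some of the libraries, were lower in the larger table. ER chaperones and ER-associated degradation had 20 of 26 members below 0 there (camera adjusted p = 0.00404) and 14 of 26 in the smaller table (0.413), with no member past the gene test, nor when adjusted over the list alone; Herpud1 had -0.30 ± 0.11 and -0.28 ± 0.12 in the authors' deposited tables. Integral ER membrane proteins had 20 of 26 below 0 in the larger table (camera adjusted p = 0.00157) and 16 of 26 in the smaller (0.413); Cyp2c29 was called in the larger (-0.44 ± 0.11 in the authors' deposited table), and when adjusted over the list alone it was lower in both. Glycosylation and ER-to-Golgi transport had 19 and 17 of 27 members below 0 (camera adjusted p = 0.0439 and 0.810), none past the gene test or when adjusted over the list alone. That call was lost at a preset correlation of 0.05 (camera adjusted p = 0.167) and without genes sharing sequence (0.0708). The difference between the tables was tested for these lists and did not pass (camera adjusted p = 0.265, 0.167 and 0.249 in that order). Targets of the integrated stress response did not pass (camera adjusted p = 0.0735 and 0.413), with 16 of 23 and 9 of 19 members above 0 and Cth called in the smaller table, also the only member past when adjusted over the list alone. The stress response list passed under 1 of 5 alternative settings in each table (lowest camera adjusted p = 0.0178 and 0.0466).

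Nuclear-encoded oxidative phosphorylation genes were higher in the larger table by small steps. There 32 of 34 members were above 0 with a median of 0.07 (camera adjusted p = 5.29e-05), and in the smaller table, 17 of 34 were, with a median of 0.00 (0.758); no member passed the gene test in either, nor when adjusted over the list alone, and Cycs (cytochrome c) had 0.23 ± 0.09 and 0.28 ± 0.11 in the authors' deposited tables. This list differed between the tables (camera adjusted p = 0.00241), although not at a preset correlation of 0.05 (0.0847). Cytosolic ribosomal proteins had 28 of 31 members above 0 in the larger table (median 0.04, camera adjusted p = 0.0207) and 14 of 31 in the smaller (0.989), with a difference that did not pass (0.0523). Cytosolic and nuclear proteins without a signal sequence had 20 of 30 above 0 in the larger table (camera adjusted p = 0.0440) and 13 of 30 in the smaller (0.823). Neither of these lists had a called member over all genes, and when adjusted over the list alone Actg1 of the cytosolic list was higher in the larger table. Both larger-table calls were lost at a preset correlation of 0.05 (camera adjusted p = 0.128 and 0.177) and without genes sharing sequence (0.0708 and 0.198).

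Genes with higher expression in female livers were lower in the larger table, with 11 of 15 members below 0 (camera adjusted p = 0.00157), and in the smaller 7 of 12 were (0.810). Cyp2a4 was called in the larger table and was the member lower in each when adjusted over the list alone. Without genes sharing sequence the call was lost (camera adjusted p = 0.787). This list differed between the tables (camera adjusted p = 0.00241), but not among all genes (0.0891) or genes of at least 5 CPM (0.375). Male-biased genes did not stand apart (camera adjusted p = 0.758 and 0.204), although Elovl3 fell in the larger table and Serpina1e rose in the smaller; 2 members were higher and 2 lower, and 1 higher, when adjusted over the list alone. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were measured in both tables, with log2 fold changes from -0.13 to 0.14 and none called in the authors' deposited tables, and were too few for a list test.

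Among marker lists of other cell types and tissues, adipocyte markers were lower in the smaller table (4 of 5 below 0, camera adjusted p = 0.00515) with 2 members lower when adjusted over the list alone, Car3 (-0.43 ± 0.11) and the lipid droplet protein Cidec (-0.48 ± 0.14 in the authors' deposited table), which hepatocytes also express. Neither passed over all genes there, the list test was lost on ranks (camera adjusted p = 0.537) and among all genes of the table (0.0791), and in the larger table it did not pass (0.0551) although Car3 did. Pancreatic acinar markers had 7 of 7 measured members above 0 in the larger table, median 0.04, with none called (camera adjusted p = 0.0145), and 2 were measured in the smaller, too few to test. Among all genes of the smaller table, including those of low mean without an adjusted p, the list did pass (camera adjusted p = 6.81e-07). Of 10 gallbladder, gut and kidney markers, 1 was measured (Lgals4, not called). Hepatocyte markers (camera adjusted p = 0.0784 and 0.153), sinusoidal endothelial markers (0.720 and 0.648), stellate cell and matrix markers (0.0735 and 0.0889), cholangiocyte markers (0.320 and 0.989) and lymphocyte and neutrophil markers (0.772 and 0.575) did not pass. Tat was the only called gene in these 5 lists, and when adjusted over the list alone 2 hepatocyte markers were higher in the larger table and 3 in the smaller, Tat among them in both. The stellate list passed under 2 of 5 alternative settings in the larger table and 1 of 5 in the smaller (lowest camera adjusted p = 0.0203 and 0.0473). The cholangiocyte list passed under 1 of 5 in the larger (0.0481).

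The remaining lists did not pass in either table in the main list test. Camera adjusted p in the larger and smaller table was 0.0502 and 0.435 for the circadian clock, 0.739 and 0.648 for secreted plasma proteins, 0.485 and 0.758 for acute phase and inflammation, and 0.182 and 0.989 for the cell cycle. It was 0.758 and 0.989 for xenobiotic metabolism, 0.332 and 0.413 for bile acid synthesis and transport, 0.881 and 0.728 for autophagy and lysosome, and 0.0735 and 0.413 for mitochondrial dynamics and stress. Called members among them were Hamp and Hamp2 of the acute phase list, Cyp2c29 of the xenobiotic list and Ppargc1a of the mitochondrial list in the larger table, and Slco1a4 of the bile acid list and Ppargc1a in the smaller. When adjusted over the list alone, the acute phase genes Crp and Saa4 were lower in the larger table, Saa4 was lower and Hamp higher in the smaller, and Cyp2c29 was lower in both. The 4 measured nuclear-retained RNAs, Neat1, Malat1, Airn and Mir99ahg, lay above 0 in both tables, from 0.05 to 0.20 and from 0.00 to 0.36 in the authors' deposited tables, with none called and too few for the test; Malat1 was higher in the smaller table when adjusted over the list alone. Among all genes of the larger table, including those of low mean, the nuclear-retained list did pass (camera adjusted p = 0.0325). In the smaller table it did not (0.0941). None of the 13 mitochondrially encoded mRNAs was measured. In the larger table, the circadian clock list passed under 2 of 5 alternative settings (lowest camera adjusted p = 0.0145). The cell cycle and mitochondrial dynamics lists passed there under 1 each (0.0259 and 0.0482).

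**Figure D3:**
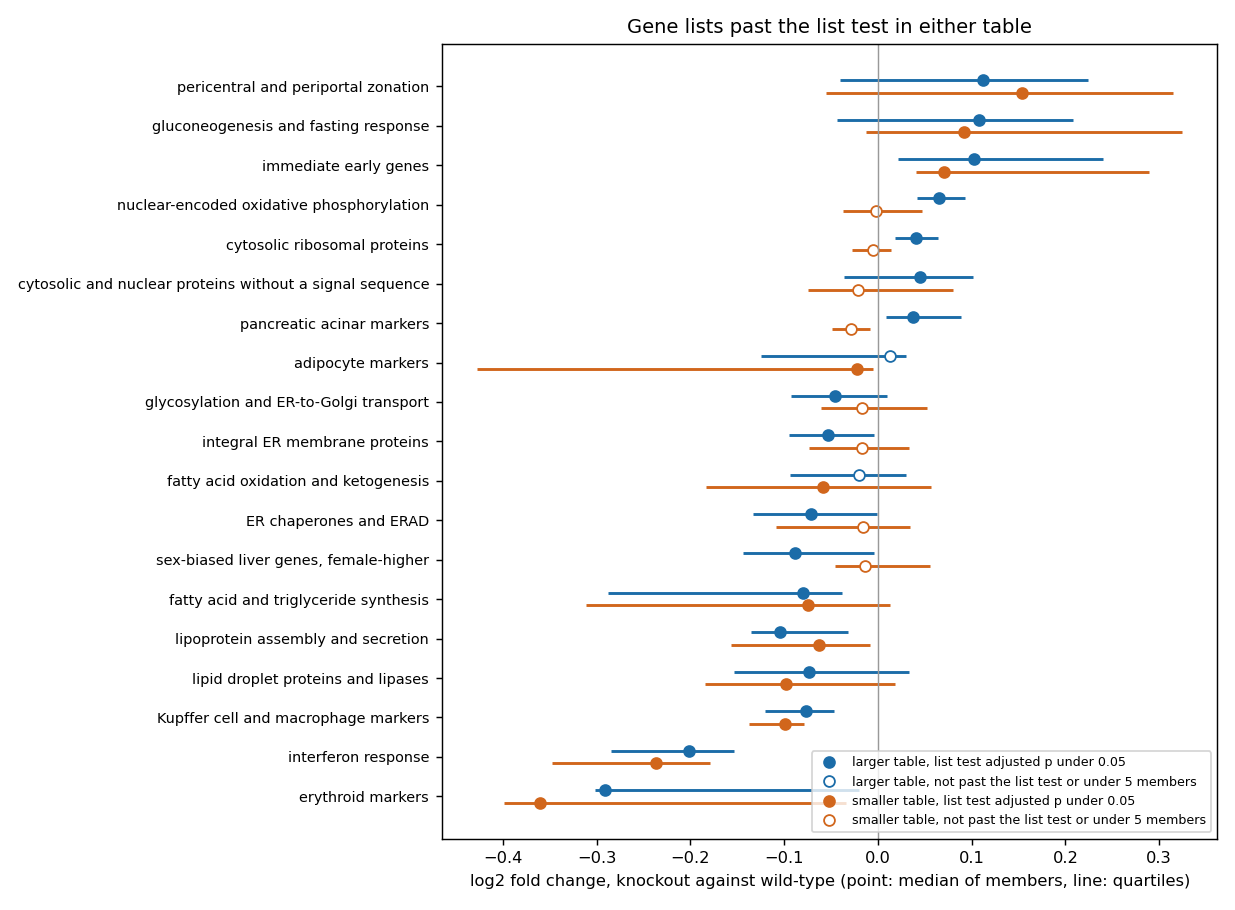
Median log2 fold change of knockout against wild-type over the measured members of each list fixed beforehand that passed the list test in either table (points; lines join the lower and upper quartiles), blue for the larger and orange for the smaller of the authors' deposited tables. Filled points passed the list test, with interferon response at -0.20 and -0.24 and erythroid markers at -0.29 and -0.36 farthest below 0.

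The tables were then compared with each other. Of 11604 genes tested in both, 7 were called higher in both, namely Tat, Etnppl, Gadd45g, Slc25a25, Ppargc1a, Mmd2 and Cpeb2. Another 7 were called lower in both, namely Cpeb4, Scd1, Serpina12, Inmt, Lgals1, Zbp1 and Gstt1. Independent lists of these sizes would share 0.0213 and 0.0238 genes. Of 36 genes called in the larger table and tested in both, 35 had the same sign in the smaller, Hamp2 excepted, and of 31 called in the smaller, 29 had the same sign in the larger, Trim30a and Pde1c excepted. Across the 11604 genes, which are not independent replicates, log2 fold changes correlated with Pearson's r = 0.685 and Spearman's rho = 0.603, and r was 0.662 without the genes under an adjusted p of 0.1 in either table. Of the 40 lists, 9 passed in both tables, with the same direction in all 9. The tables may come from the same mice, so they do not replicate each other independently.

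The difference between the tables was tested gene by gene, and 2 genes passed. Ren1 (ENSMUSG00000070645; GRCm38 chromosome 1, 133350510 to 133360325, plus strand) was at 0.64 ± 0.10 in the authors' deposited larger table and 0.05 ± 0.04 in the smaller, a difference of -0.59 ± 0.11 (z test, adjusted p = 0.00221). Trim30a (ENSMUSG00000030921; GRCm38 chromosome 7, 104409025 to 104465193, minus strand) was at -0.13 ± 0.12 in the authors' deposited larger table and 0.69 ± 0.12 in the smaller, a difference of 0.82 ± 0.17 (z test, adjusted p = 0.0104). Its mean count was 254 in the larger table and 5222 in the smaller. The standard error of Ren1 in the smaller table is far under the median of 0.128, as for estimates drawn strongly towards 0, so its difference is uncertain. With means of at least 5 CPM in both tables, or with a difference of Wald statistics, Trim30a alone passed. Pde1c (z test, adjusted p = 0.114), Fmn2 (0.527) and Scd2 (0.713) did not pass, so a call in a single table does not show a difference for them.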

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

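The tests of shared sequence, of Wald statistics and of their spread were chosen after the results they bear on had been seen.

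Ren1 stood out because its genotype difference was larger in the larger table than in the smaller, by -0.59 on the log2 scale (smaller minus larger), and Trim30a because the difference went the other way, by 0.82. Reads shared with other genes were weighed as a technical source. The mean level of 1134 of 11067 genes with a mean of at least 100 in either table differed over 4-fold between the tables, and 61.1% of these genes share over 25% of their sequence words with another gene, against 1296 of the other 9933 genes, so shared reads may have been counted differently in the 2 tables. For Ren1, reads shared with another annotated gene are argued against, since 0.55% of its words are shared and its level differed by 1.55-fold. A copy of the gene that is missing from the reference annotation would not be seen by this measure, so reads from such a copy stay open. With a difference of Wald statistics 1 gene passed, Trim30a, and Ren1 did not; whether unequal moderation of its fold changes lies behind its difference was not tested. For Trim30a, shared reads cannot be told apart from a difference between the RNA preparations, with 11.94% shared words, between the bounds set of 5% and 25%, and a mean 20.6 times higher in the smaller table; such a difference stays open and untested for Ren1 too.

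The list of nuclear-encoded oxidative phosphorylation genes differed between the tables (camera adjusted p = 0.00241), higher in the larger table, but not at a preset correlation of 0.05 (0.0847). The list of female-biased liver genes differed as well (camera adjusted p = 0.00241), lower in the larger table, but not among all genes (0.0891) or genes of at least 5 CPM (0.375).

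Another pattern is that the Wald statistics of the tables vary together, with r = 0.691 over 11604 genes, while fewer genes than chance gives have an unadjusted p under 0.05 (3.62% and 4.11%). The robust SD of the statistics was 0.75 and 0.84, which restates the second part, so standard errors wider than the spread of unchanged genes cannot be told apart from the moderation of the fold changes. Whether the same mice lie behind both tables cannot be told apart from broad small genotype effects: among 4704 genes with p above 0.5 in both tables, r was 0.16, between the bounds of 0.1 and 0.3, and both would raise it. Limiting both statistics to small values lowers r by itself, so 0.16 does not show a weaker relation among unchanged genes.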

How the results depend on the processing

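The settings of no mean filter, a mean of at least 5 CPM for calls, lists and correlation, and the correlation over called genes were chosen in advance; the others were chosen after seeing the data. No fixed list that passed its test changed direction under these settings; the lists added later were not part of this check. Dividing the statistics by their robust SD raised the calls to 97 higher and 128 lower in the larger table (13 and 29 as deposited) and to 43 and 53 in the smaller (19 and 12), and all genes called as deposited stayed among them; fewer false calls are not implied. With no mean filter 12 and 20 genes were called in the larger table and 16 and 10 in the smaller, and 17 calls ended, all with adjusted p from 0.0501 to 0.0808, since more genes were adjusted for. Among genes of at least 5 CPM in both tables, 1 gene differed, since Ren1 lies below that mean, and with a difference of Wald statistics 1 did, against 2; Trim30a stayed in both. The correlation between tables was 0.853 over genes called in either, which were selected for size, against 0.685. Lists past the test in the larger table numbered 11 without genes sharing sequence, against 17. There 34 lists had enough members, against 36, and the female-biased list was still tested but lost its call (camera adjusted p = 0.787). Whether lost calls rested on the members sharing sequence or on smaller lists was not tested. In the smaller table, 5 lists passed on ranks, against 11, since ranks give single large members less weight. For differences between the tables, the number of lists was 1 each at preset correlation 0.05, among all genes, among genes of at least 5 CPM and without genes sharing sequence, against 2. On ranks that number was 3. Without sharing genes too few female-biased members were left to test for a difference between the tables. No paired analysis was possible because the deposited columns carry no replicates. For the same reason the other planned settings (refits with count models and with voom, other normalisations, all 8 libraries together, pseudocounts, omission of each library, blocks by replicate or description number, fry and an estimated correlation, and all settings of ER against total liver) were not run. Without values per library the depth behind a single gene limits the tables only through the deposited standard errors.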

Other observations

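The amino acid list and the portal and central lists, and the tests on them, were chosen after the gene results had been seen, so they are not independent of them; apart from 1 addition named below, the bounds of each test were written before its value was known.

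Enzymes of amino acid breakdown and the urea cycle were higher in the knockout in both tables. Of 40 listed genes, 31 of 37 measured in the larger table and 30 of 36 in the smaller lay above 0, with medians of 0.18 and 0.16 (camera adjusted p = 1.87e-21 and 2.57e-18 over 3 added lists). Tat and Etnppl passed the gene test in the larger table, and Tat, Etnppl, Cth, Got1 and the ornithine carrier Slc25a15 in the smaller, per the authors' deposited tables. Etnppl, the ethanolamine-phosphate phospho-lyase, acts on an ethanolamine compound and not on an amino acid. Its call is therefore no evidence for amino acid breakdown. Gldc, of glycine cleavage, had 0.39 ± 0.11 and 0.44 ± 0.12 in the authors' deposited tables without passing. A hypothesis is that the rise is shared by the pathway beyond its called genes. The members called in neither table still ranked above other genes, with a camera p on ranks of at most 8.3e-05 over both tables, which met the bound written beforehand. The list itself was chosen with the values of these members open to view, so this rank does not decide the hypothesis. Fasting raises many of these genes, and the feeding state at collection, known for the ER preparations alone, was not tested.

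The zonation list divides into genes of the portal and the central side. Portal members lay above 0 in 9 of 11 and 10 of 11 cases, with medians of 0.21 and 0.22 (camera adjusted p = 3.63e-07 and 4.01e-08). A hypothesis of opposite shifts would need central members below 0. Their medians were -0.02 and -0.05 (10 and 9 measured, camera adjusted p = 0.0889 and 0.523), the higher being -0.02. The bound written beforehand asked for a median below 0 in both tables and was met; a bootstrap interval below 0 was asked for in addition and was not reached, and members lay on both sides of 0, so the hypothesis stays open. Of the portal members, 4, namely Ass1, Asl, Arg1 and Cps1, are also urea cycle enzymes. Hal, Sds and Gls2 of the portal side encode enzymes of amino acid breakdown too. The portal rise is therefore not separate from that of amino acid breakdown.

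The lower interferon-response genes were weighed against a retained chromosome segment and against a smaller share of macrophages. A segment of another strain's genome around Cpeb4 could alter genes inside it, but 25 of the 26 members lie outside 20 Mb of the gene. Their median was -0.21 in the larger table (95% bootstrap interval -0.27 to -0.16) and -0.24 in the smaller (-0.31 to -0.18). With 1 member inside, leaving it out could hardly move the medians of all 26 (-0.20 and -0.24), so these values are no separate test. The positions alone argue against a direct action of the segment on most members. A regulator of the pathway inside the segment was not tested. Fewer macrophages would lower their markers at least as far, yet the interferon median lay below the macrophage median in both tables. The differences were -0.12 (interval -0.19 to -0.06) and -0.14 (-0.19 to -0.07), at similar median standard errors (0.118 and 0.116 in the larger table). All these intervals came from resampling list members, which may move together, and they hold no spread between mice or libraries. They describe these members and do not by themselves exclude a smaller share of macrophages. A biological origin in the genotype may remain as a hypothesis, as may a difference in housing or infection between the mice, which these data do not address. Strain differences elsewhere in the genome were not examined, for these genes or for the other called genes.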
